A study of Mus musculus with 2 samples.

How the data were processed

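Total RNA from mouse cells of 2 samples was purified with a column kit, copied into cDNA from a poly(A) primer carrying a T7 promoter, transcribed into biotin-labelled cRNA and hybridised to 1-colour arrays, per the labels' protocols. The labels name 1 sample as lymphoma cells in medium with serum and 1 as lymphoma cells co-cultured with endothelial cells. They do not give the lymphoma line, the source or species of the endothelial cells, the length of culture, or whether the cell types were separated before RNA was taken. The deposited table holds the authors' values as a linear intensity per probe set, with 45101 probe sets on each array. The array software, the background correction and the normalization are not given in the sources used here. From the values, the mean after trimming 2% at each end was 500 on both arrays while their medians were 36.9 and 50.7, a pattern that global scaling to a common trimmed mean would leave. This is inferred from the numbers and stated by no label.

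Probe sets were named through the platform annotation of the array, with symbols updated through the gene number to the RefSeq annotation of GRCm38.p6. Of the probe sets, 34958 had 1 gene symbol, 932 had several, 9160 were not listed with a symbol and 64 were controls. These groups overlap, since some controls were also listed with a symbol, and controls with 1 symbol were not left out of the genes. Of the 34958, 34754 took their symbol from the RefSeq annotation through the gene number, whether or not it changed. No gene was named from a probe set with several symbols. No coordinates are given, since the values carry no genome build.

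Intensities were put on the log2 scale after every value below the floor, the pooled median of all values of both arrays (44.3), had been set to it. The 27 bacterial control probe sets outside the spike mix reached at most 21.6 and 21.7. Each gene took the probe set with the highest mean log2 value, so different probe sets of a gene can disagree and the value is that of the brightest. A gene counted as measured when that probe set was above the floor on at least 1 array, and as higher or lower when the log2 difference, co-culture minus serum, reached 1 in size. A fold against a value at the floor is a lower bound and is written as at least that fold.

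With 1 array per group there is no test between groups. Error was described by the pooled SD of log2 differences among measured probe sets of the same gene, which was 0.67 at a mean intensity below 200 (1537 genes) and 0.57 at 200 or more (3943 genes). It covers hybridisation and probe error, not the spread between cultures. Of 209 higher genes with another measured probe set, 97 (46.4%, exact 95% interval 39.5 to 53.4) had another one at least 2-fold higher, and of 473 lower genes 193 (40.8%, 36.3 to 45.4) had another one at least 2-fold lower. The Spearman correlation across the 19913 probe sets above the floor on both arrays was 0.934; probe sets are not independent replicates.

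The 35 gene lists, the floor, the 2-fold limit, the naming rule and 7 alternative settings were fixed before the data were examined. For each list with at least 5 measured members, the median log2 difference was placed as a percentile among 10000 random lists of the same size, matched on mean log2 intensity in 20 bins. A list was said to stand apart below the percentile 2.5 or above 97.5. This describes these 2 arrays and is not a test of the conditions. Several lists share members. A further 12 lists, for cell lineages and pathways, and 2 further settings were chosen after the data were seen.

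Genes were named by a rule. It took the 12 genes with the highest and the 12 with the lowest log2 difference past 2-fold, without clone and gene-model symbols and without genes that had another measured probe set moving the other way. From each list it took up to 4 members with the largest difference past 2-fold, or 2 members where none reached 2-fold. It also took Notch1, Notch2, Hes1, Hey1, Cd44, Igf1r, Csf1r, Fgfr1, Jag1, Myc, Pecam1 and Cdh5, whatever their values, and a further gene that is not reported here. Of 95 genes named by the rule past 2-fold, 44 had another measured probe set, and for 22 of these another one lay within 2-fold or on the other side. Other genes in the text, among them Ptprc, Cd79a, Cd79b, Pax5, Cd24a, Cd74, Ctss, Kdr, Lyve1, Nrarp, Hey2, Dtx1, Ptcra, Gapdh, Tfrc, Cd47, Ltbp1, Id2, Id3 and Smad3, were chosen after their values were seen.

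The alternatives were floors at percentiles 25 and 75 of all values, a pseudocount of 16 in place of the floor, subtraction of the median difference, quantile normalization, the mean over probe sets, leaving out probe sets whose identifier marks shared sequence, and, chosen later, a floor at 200 and scaling to the bacterial hybridisation spikes. The steps were tested on simulated data for this comparison. With a noise SD of 0.2, over 11078 genes, 100% of 200 genes raised 4-fold and 99% of 200 genes lowered by 1.5 log2 units were called, 0 of 10678 unchanged genes were called, as a limit that far above the noise fixes in advance, and 7 of 100 random lists of unchanged genes stood apart. With the noise SD set to the 0.60 found between probe sets of 1 gene, over 11373 genes, 930 of 10973 unchanged genes (8.48%) were called, 578 higher and 352 lower, and 95.5% of the raised and 80% of the lowered genes. Of the unchanged genes with another measured probe set, 20 of 285 called higher (7.02%) and 5 of 153 called lower (3.27%) were backed by it at 2-fold. That SD holds differences between probe sets as well as noise. The simulated noise is independent between probe sets and lies on the co-culture array alone. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.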

Results

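Gene expression was measured in mouse cells labelled as lymphoma under 2 culture conditions, with 1 array per condition. The first array carried RNA from cells labelled as lymphoma grown in medium with serum, and the second carried RNA from cells labelled as lymphoma grown together with endothelial cells, the cells that line blood vessels. The comparison asks which genes differ between the 2 cultures of cells of that label. The label of the co-culture sample does not name its medium, so medium and endothelial cells may both differ. Both arrays held 45101 probe sets, and 47.3% of them on the serum array and 52.7% on the co-culture array lay above the floor, an intensity of 44.3. Of 18194 genes with a probe set, 11560 (63.5%) lay above the floor on at least 1 array and are called measured. The number of arrays limits the precision: there are no replicates, so no difference below has a test against culture-to-culture spread and no p-value is given. Different probe sets of 1 gene, the measure of error used for genes here, differed with a pooled within-gene SD of 0.60 on the log2 scale over 5480 genes. The 3′ to 5′ intensity ratio of beta-actin, a sign of RNA length, was 3.56 on the serum array and 2.05 on the co-culture array, that of Gapdh was 2.54 and 1.88, and that of the transferrin receptor Tfrc was 13.2 and 5.03. This gap, in 1 direction for the 3 controls, stands beside every group difference that follows.

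Most genes that define B cells and other leukocytes were near background on both arrays, although both samples are labelled lymphoma. Ptprc, the CD45 antigen of nearly all white blood cells, had an intensity of 21.5 on the serum array and 3.14 on the co-culture array. Cd79a and Cd79b, the signalling chains of the B cell receptor, had 34.7 and 9.15 on the serum array and 30.9 and 1.29 on the co-culture array, and Pax5, the transcription factor that keeps B cell identity, had 2.52 and 2.16. Of 19 B-lineage identity genes with a probe set, 6 were measured, and only Cd24a, a surface protein of many immature cell types, reached an intensity of 200 (3486 and 4981). Of 25 pan-leukocyte genes, a list chosen after the data were seen and holding Ptprc, Cd79a, Cd79b and Pax5, 21 were below the floor on both arrays, and the highest intensity of the rest was 139. Some genes used by leukocytes were bright: the invariant chain Cd74 (726 and 477), the protease Ctss (1535 and 1337), the BAFF receptor Tnfrsf13c (528 and 200) and the lymphoid and neural transcription factor Bcl11b (1843 and 1419). Genes of proliferating cells were bright on both: all 27 S phase genes and 29 of 30 genes of Myc and ribosome biogenesis were measured, although Myc itself, a growth regulator, was not (23.8 and 9.34). The 2 samples are therefore named by their labels throughout, as the array labelled serum culture and the array labelled endothelial co-culture.

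**Figure D1:**
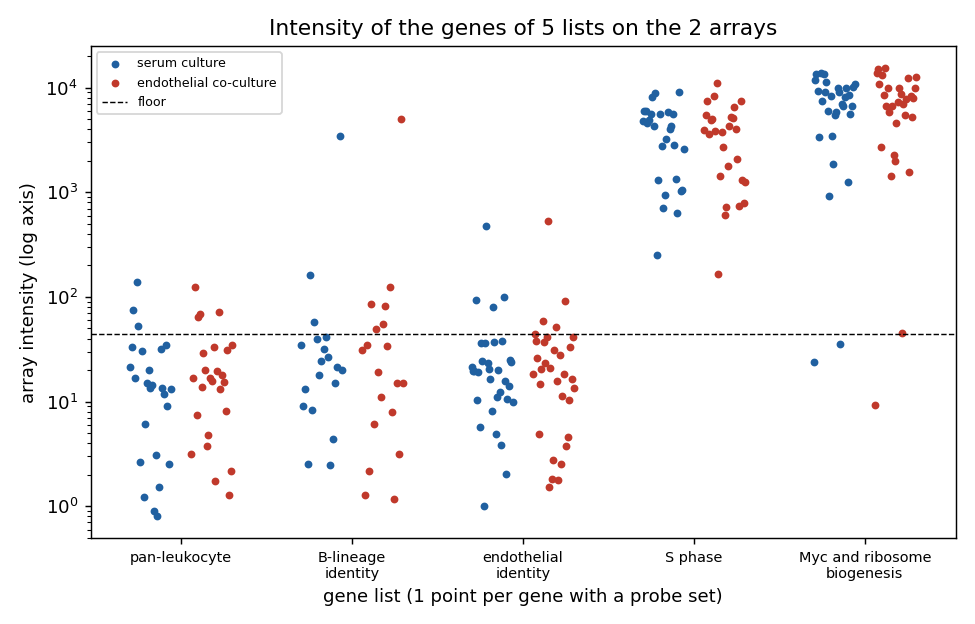
Array intensity (log axis) of each gene with a probe set in 5 lists, with the array labelled serum culture in blue, the array labelled endothelial co-culture in red and the floor of 44.3 as a dashed line. Of the 25 pan-leukocyte genes 21 lie below the floor on both arrays, while all 27 S phase genes lie above it.

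On the array labelled endothelial co-culture, 523 genes were at least 2-fold higher and 1152 at least 2-fold lower than on the array labelled serum culture, and 9885 lay within 2-fold. The balance depends on the floor: at the lower floor of percentile 25, 2029 genes were higher and 1599 lower, a share higher of 55.9% against 31.2%. Cyp1a1, a cytochrome that oxidises foreign aromatic compounds, was 35.1-fold higher (50.8 to 1783). Msx1, a homeobox factor of embryonic patterning, was at least 19.3-fold higher, Htra1, a secreted serine protease, 17.7-fold (361 to 6377), and Tmprss2, a membrane-bound serine protease, at least 15.8-fold. Slc4a1, the red cell anion exchanger, was at least 14.5-fold higher, Spred2, an inhibitor of Ras signalling, 14.3-fold, and Pmepa1, a TGF-beta target that dampens that pathway, 13.8-fold. Further down came the transcription factor Sp6 (at least 10.9-fold, but a log2 difference of 0.46 by another probe set), the extracellular protein Coch (at least 10.3-fold), Irf2bpl (10.3-fold), the RNA-binding protein Lin28a of early embryonic cells (8.98-fold) and the gap junction gene Gja3 (at least 8.94-fold).

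Among the genes lower in co-culture, Krt75, a keratin of hair follicles, was at least 17.3-fold lower and Rnase1, a secreted ribonuclease, 16.02-fold lower (960 to 59.9). The non-coding Foxl2os was at least 12.7-fold lower, the calcium-binding Tesc 12.1-fold, and Ptgds, which makes prostaglandin D, 10.2-fold (2150 to 211). Mbp, the gene of a myelin protein, was 9.96-fold lower, Rai2 9.88-fold, the photoreceptor gene Rd3 at least 9.68-fold, Fam149a at least 9.31-fold and Bmp7, a bone morphogenetic protein ligand, 9.23-fold (1140 to 123). Bahcc1 was 8.96-fold lower, and Ldhb, the lactate dehydrogenase subunit of aerobic tissues, 8.73-fold lower with all 4 of its measured probe sets lower. Another probe set of Mbp gave a log2 difference of -0.16, and Irf2bpl had a log2 difference of 0.38 once probe sets with shared sequence were left out. In simulated arrays with the noise seen between probe sets of 1 gene, 578 unchanged genes passed as higher and 352 as lower. The measured counts were 523 and 1152. The simulated noise lay on the co-culture array alone and each gene took its brightest probe set, which favours higher calls. Neither count can therefore be set against its simulated one alone, and a share of noise in both is not excluded. Of the unchanged genes with another probe set, 7.02% of those called higher and 3.27% of those called lower were backed by it. The simulated noise was independent between probe sets, which fixes such low shares in advance. On the real arrays the shares backed were 46.4% and 40.8%, a gap that does not show how many calls are real. There, all other measured probe sets moved the same way for 171 of 209 higher genes and for 302 of 473 lower genes. Scaling to the hybridisation spikes, an alternative chosen after the data were seen, gave 349 higher and 1620 lower genes, a share higher of 17.7%, and moved the median difference of all measured genes from -0.06 to -0.26.

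**Figure D2:**
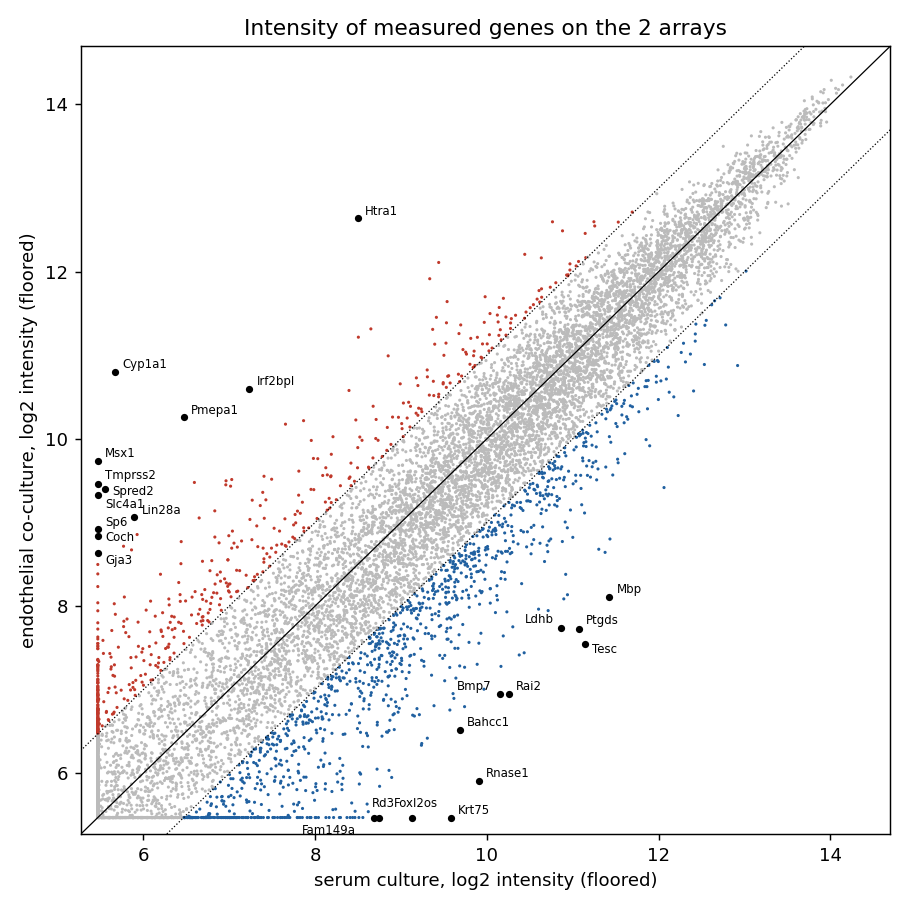
Log2 intensity of the 11560 measured genes on the array labelled serum culture (x axis) and the array labelled endothelial co-culture (y axis), with values below the floor set to it. Red points are the 523 genes at least 2-fold higher in co-culture, blue points the 1152 at least 2-fold lower, dotted lines mark 2-fold, and the named black points are the 12 genes farthest from equality on each side by the naming rule.

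Genes of the TGF-beta and BMP response were higher in co-culture as a group. Of 18 measured members 7 were at least 2-fold higher and 0 lower, the median log2 difference was 0.59, and 0 of 10000 random lists of the same size and level had a median as high. Ccn2, a matrix-associated growth factor, was at least 5.03-fold higher, Id1, an inhibitor of differentiation factors, 4.95-fold (114 to 563), Smad7, the inhibitory SMAD, 3.84-fold (661 to 2537) and Skil, a SMAD co-repressor, 3.56-fold (1739 to 6191). The other members past 2-fold were Ltbp1 (2.96-fold), Id2 (2.48-fold) and Id3 (2.08-fold), while the signal transducer Smad3 had a log2 difference of -0.87. The list of drug efflux and detoxification genes also had a higher median (0.37, percentile 99.8). Of its 16 measured members 4 were at least 2-fold higher and 0 lower. Its measured efflux transporters did not move together. Abcg2 and Abcc4 had log2 differences of 0.85 and 0.54, but Abcb1b had -0.43, Abcc1 -0.40 and Abcc5 -0.72 (up to 1.75 by another probe set). Nqo1, a quinone reductase, was 3.63-fold higher (739 to 2679), Hmox1, which degrades haem, 3.29-fold (1010 to 3326), Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, 2.13-fold, and the glutathione transferase Gstt1 at least 2.03-fold.

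The lists of oxidative phosphorylation and of hypoxia and glycolysis had slightly lower medians in co-culture, with most members within 2-fold. Of 27 measured oxidative phosphorylation genes 3 were at least 2-fold lower and 0 higher, with a median log2 difference of -0.22, and 1 of 10000 random lists had a median as low. Those 3 were Ndufv2 and Ndufa5 of complex I (2.02-fold each) and Sdhb of complex II (6436 to 3215). Of 26 measured genes of hypoxia and glycolysis 4 were lower and 1 higher, with a median of -0.30 and a percentile of 0.31. Adm, a vasodilator peptide induced by low oxygen, was 5.81-fold lower (1934 to 333; just under 2-fold by another probe set), Ndrg1 2.96-fold (0.10 on the log2 scale by another probe set) and Bnip3, a mitophagy receptor, 2.27-fold, while the lactate exporter Slc16a3 was 2.54-fold higher. The list of hypoxia and glycolysis no longer stood apart when probe sets with shared sequence were left out.

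The unfolded protein and amino acid response list had 4 of 25 members lower and 1 higher, a median of -0.22 and a percentile of 2.91, and did not stand apart, though it did on the lower side in 4 of 9 alternative settings. The stress transcription factor Ddit3 was 3.23-fold lower (0.20 on the log2 scale by another probe set), Chac1, which degrades glutathione, 2.64-fold and Herpud1, of endoplasmic reticulum protein degradation, 2.34-fold (-0.51 by another probe set), while the protein disulfide isomerase Pdia4 was 5.02-fold higher. Of 17 cholesterol synthesis genes Mvd, of the mevalonate pathway, was 2.30-fold lower and 16 lay within 2-fold (median 0.00, percentile 58.2). All 13 heat shock protein genes lay within 2-fold by their brightest probe sets (median 0.11, percentile 82.4). Hspa1b had a log2 difference of 0.84 (2.06 by another probe set) and Dnaja1 had -0.59.

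Some Notch target genes were at least 2-fold higher in co-culture and others were not. Hes1 and Hey1, transcription factors that Notch activates, were at least 3.30-fold and 3.18-fold higher (829 to 2632 for Hey1), the ligand Jag2 was 2.29-fold higher (0.41 on the log2 scale by another probe set) and Lfng, which modifies Notch receptors, at least 2.27-fold. Notch1 and Notch2 had log2 differences of -0.08 and -0.10, and the ligand Jag1 had 0.66 (-0.32 by another probe set). Of the other targets, Nrarp had 0.98, Hey2 -0.18, Dtx1 -0.19 and Ptcra -0.47. Across the 19 measured Notch pathway genes 4 were higher and 0 lower, but the median was -0.08 at a percentile of 43.7, so the list did not stand apart. The FGF and IGF axis had 4 of 13 members lower and 1 higher (median -0.50, percentile 3.98) and did not stand apart either, though it did on the lower side in 3 of 9 alternative settings. Igfbp5 and Igfbp4, which bind insulin-like growth factors, were 3.94-fold and 2.27-fold lower, and the insulin receptor substrate Irs1 was 2.85-fold lower. Fgf4 was at least 2.80-fold higher. The receptors Fgfr1 and Igf1r had log2 differences of 0.56 and 0.66. Other probe sets gave 1.29 for Fgfr1, and -0.34 and 0.77 for Igf1r. Another measured probe set of Igfbp5 was higher in co-culture, by 1.58 on the log2 scale, and another of Igfbp4 had -0.47.

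Stem and progenitor surface genes, adhesion genes and immediate early genes had higher medians in co-culture. The 6 measured stem and progenitor genes had a median of 0.60 (percentile 99.5). Epcam, an epithelial adhesion molecule, was 2.15-fold higher (0.10 on the log2 scale by another probe set). The laminin receptor subunit Itga6 was 2.13-fold lower, though another probe set gave a log2 difference of 0.77. The hyaluronan receptor Cd44 had a log2 difference of 0.54, or 1.79 by another probe set. Csf1r, the macrophage growth factor receptor, was not measured (11.8 and 1.67). The 13 adhesion and integrin genes, which share Cd44 and Itga6 with that list, had a median of 0.54 (percentile 99.8), yet 2 were at least 2-fold higher and 3 at least 2-fold lower. F11r, a tight junction molecule, was 3.65-fold higher and the tetraspanin Cd9 2.45-fold higher, while the tetraspanin Cd151 was 2.17-fold lower and Cd47, a signal against phagocytosis, 2.13-fold lower (-0.07 on the log2 scale by another probe set). Of 18 immediate early genes 3 were higher and 0 lower (median 0.29, percentile 98.5): the phosphatase Dusp2 by 3.10-fold, the RNA-binding Zfp36 by 2.82-fold and the AP-1 subunit Fosl1 by at least 2.42-fold. These lists stood apart in 7, 7 and 4 of 9 alternative settings, in that order. Each count includes the subtraction of the median difference, which moves all genes alike and cannot change a percentile. It also includes the scaling to spikes, which is such a shift except near the floor. Cd151 had a log2 difference of 0.26 once probe sets with shared sequence were left out.

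**Figure D3:**
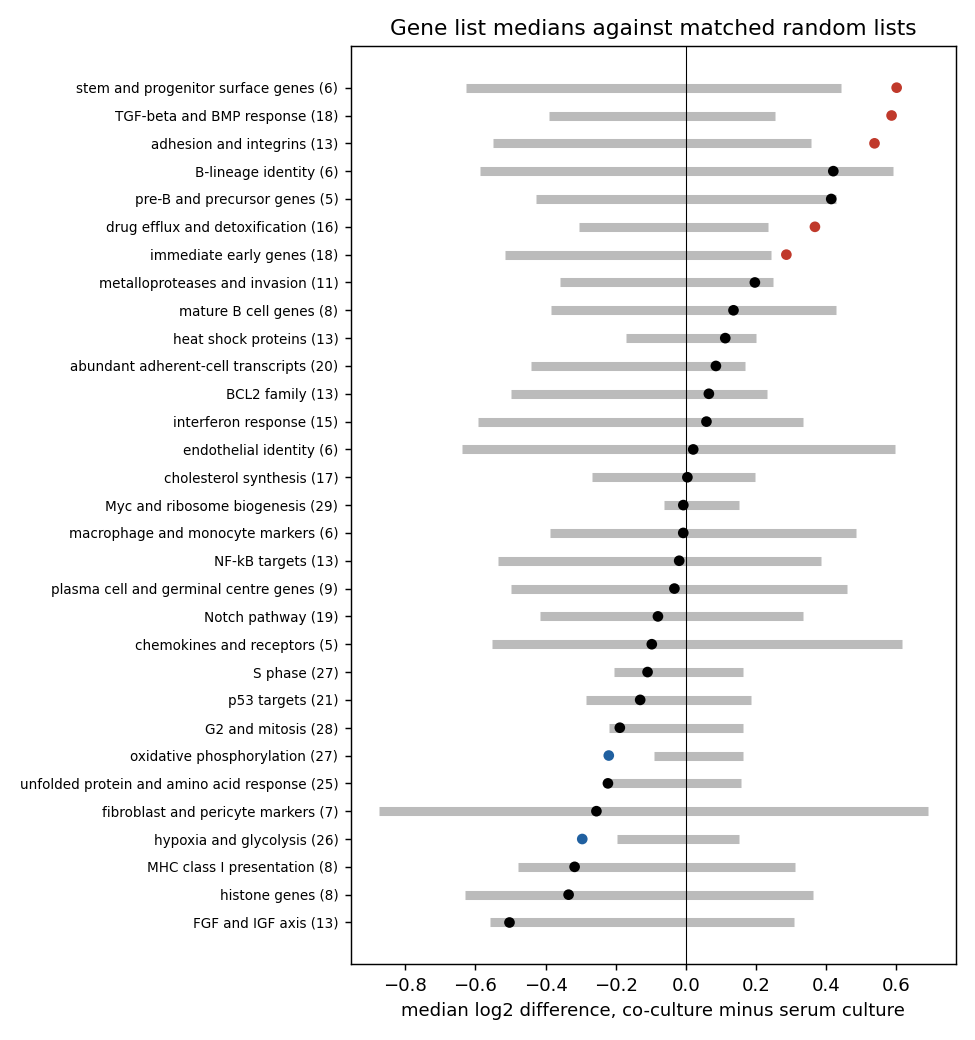
Median log2 difference, co-culture minus serum culture, of 31 gene lists (points, with the number of measured genes in brackets) against the central 95% of medians of 10000 random lists matched on level (grey bars). Red points mark the 5 lists that stood apart on the higher side, from 0.29 for immediate early genes to 0.60 for stem and progenitor surface genes, and blue points the 2 on the lower side.

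Of the 31 lists 7 stood apart, against 1.55 that chance gives at these limits. That number takes the genes of a list to move independently, as in random lists, which genes of 1 pathway may not do. In the simulated arrays with the lower noise 7 of 100 random lists of unchanged genes stood apart. None of the 4 lists of growth and division stood apart, with 0 members higher and 5 lower, though G2 and mitosis and histone genes each did on the lower side in 1 of 9 alternative settings. All 29 measured genes of Myc and ribosome biogenesis lay within 2-fold (median -0.01, percentile 16.3), where Polr1b of RNA polymerase I had 0.64 and the ribosome assembly factor Bop1 -0.61 (0.38 by another probe set). In S phase 1 of 27 genes was lower, the chromatin assembly factor Chaf1b by 2.06-fold (median -0.11, percentile 14.6). In G2 and mitosis 2 of 28 were lower, the spindle checkpoint kinase Ttk by 2.05-fold and the proliferation marker Mki67 by 2.01-fold (median -0.19, percentile 4.67). Another measured probe set of Ttk was higher in co-culture, by 0.86 on the log2 scale. Of 8 histone genes 2 were lower, H2bc21 by 2.80-fold (-0.24 on the log2 scale by another probe set) and H2ax by 2.61-fold (median -0.33, percentile 18.2).

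Cell cycle arrest and death genes moved in both directions. Cdkn1a, the p21 inhibitor of cell division, was 3.40-fold higher (1390 to 4727), whereas the DNA damage gene Gadd45a was 2.59-fold lower and the death receptor Tnfrsf10b at least 2.63-fold lower. The list of p53 targets had 1 of 21 higher and 2 lower (median -0.13, percentile 21.7). Bcl2, which blocks apoptosis, was at least 2.77-fold higher, while Hrk and Bok, which promote it, were 2.83-fold and 2.19-fold lower. Other probe sets gave log2 differences of 0.54 for Bcl2 and -0.31 for Hrk. The BCL2 family had 1 of 13 higher and 2 lower (median 0.07, percentile 79.9), and neither list stood apart.

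The lists of MHC class I presentation, interferon response, NF-kB targets and chemokines did not stand apart. Of 8 MHC class I genes 3 were lower and 0 higher (median -0.32, percentile 8.95): H2-D1 by 2.78-fold, H2-K1 by 2.13-fold and the peptide transporter Tap1 by at least 2.13-fold. H2-D1 belongs to a family of near-identical genes and had a log2 difference of 0.10 once probe sets with shared sequence were left out. Of 3 measured MHC class II genes 1 was lower, H2-DMa by at least 2.10-fold. Of 15 interferon response genes 4 were lower and 3 higher (median 0.06, percentile 75.3), with Isg20 at least 3.70-fold, the antiviral Rsad2 3.16-fold and Usp18 2.29-fold lower, and the GTPase Irgm1 2.51-fold higher. Of 13 NF-kB targets 2 were lower and 1 higher (median -0.02, percentile 51.6), the inhibitor Nfkbie by at least 7.09-fold and Tnip1 by 2.38-fold lower and Ier3 by 2.02-fold higher. All 5 measured chemokines and receptors lay within 2-fold (median -0.10, percentile 23.4), with log2 differences of -0.73 for Cxcl9 and 0.60 for Cxcl1, both with a value at the floor.

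The measured B cell genes were mostly dim. In B-lineage identity the kinase Blk was at least 2.84-fold higher (27.0 to 126) and 5 of 6 lay within 2-fold (median 0.42, percentile 86.2). Of 5 pre-B and precursor genes Lef1, a Wnt effector, was 2.02-fold higher and Myb, a progenitor transcription factor, 3.73-fold lower (median 0.41, percentile 97.1). Another measured probe set had a log2 difference of -0.30 for Lef1 and -0.65 for Myb. Of 8 mature B cell genes 2 were lower, the BAFF receptor Tnfrsf13c by 2.64-fold and the immunoglobulin heavy chain Ighm by at least 2.31-fold (median 0.14, percentile 61.8). Of 9 plasma cell and germinal centre genes 2 were lower, the receptor S1pr2 by 2.30-fold and the repressor Bcl6 by 2.07-fold (median -0.03, percentile 37.8).

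No measured endothelial marker was at least 2-fold higher on the array labelled endothelial co-culture. The junction proteins Pecam1 (21.3 and 18.4) and Cdh5 (19.6 and 44.1), the VEGF receptor Kdr (19.5 and 38.4) and Lyve1 (14.0 and 33.3) lay below the floor on both arrays. At the lower floor of percentile 25 (12.8), 27 endothelial identity genes were measured and 2, Cdh5 (1.17) and Lyve1 (1.25), were at least 2-fold higher, with 3 lower (median 0.30, percentile 33.0). At the main floor, of 32 endothelial identity genes 6 were measured, with 0 at least 2-fold higher and the related receptor Flt1 at least 2.11-fold lower (median 0.02, percentile 48.5). Of 20 measured adherent-cell transcripts 4 were higher and 3 lower (median 0.09, percentile 90.8). Fstl1, a secreted glycoprotein, was 7.38-fold higher, the laminin chain Lamb1 5.29-fold (0.64 on the log2 scale by another probe set) and Ccn2 at least 5.03-fold, while the basement membrane collagen Col4a1 was 6.82-fold lower (1679 to 246). Of 7 fibroblast and pericyte markers the matrix protein Fbln1 was 3.10-fold lower (0.25 on the log2 scale by another probe set) and 6 lay within 2-fold (median -0.25, percentile 37.1). Of 11 metalloprotease and invasion genes Mmp19 was at least 2.87-fold higher and 10 lay within 2-fold (median 0.20, percentile 93.8).

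Markers of other blood cells were sparse. All 6 measured macrophage and monocyte markers lay within 2-fold (median -0.01, percentile 31.2), with -0.58 for Csf3r and 0.57 for Adgre1, each with a value at the floor. Of T and NK cell markers 3 were measured and lay within 2-fold, among them Cd247 at 0.89 and the transcription factor Bcl11b at -0.38 (1843 and 1419), or 1.22 by another probe set. Cpa3 was the only measured granulocyte and mast cell marker (0.07), and of 2 measured red cell markers 1, Slc4a1, was higher.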

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

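The tests of array scaling, of RNA length, of weak detection and of RNA from other cells were chosen after the results they bear on had been seen, and the test of signal level was chosen when the counts it concerns were known but not the matched share.

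As a source of the 523 genes at least 2-fold higher in co-culture, RNA of endothelial cells left in the sample would raise endothelial and adherent-cell transcripts together. Higher were 0 of 6 and 4 of 20 measured members (15.4% together). The upper exact 95% bounds were 45.9% and 43.7%, below the 50% set beforehand for a main source. These bounds treat genes as independent. Adherent-cell members already bright on the serum array, such as Sparc (5889) and Tpm1 (3744), could hardly double. The 4 that rose were dimmer there, such as Fstl1 (96.6) and Lamb1 (100), so this count can miss endothelial RNA. A smaller share is not excluded. At the floor at percentile 25, where Cdh5 and Lyve1 pass 2-fold, 2 of 27 and 5 of 28 were higher (upper bounds 24.3% and 36.9%), whereas without shared-sequence probe sets too few were left (0 of 4 and 4 of 15, upper bounds 60.2% and 55.1%). A difference in array scaling cannot be told apart for part of them: the 18 hybridisation spikes were brighter in co-culture by 0.07 to 0.31 on the log2 scale, and subtracting their median left 349 of the 523 genes past 2-fold, subtracting the highest 258 (49.3%). A difference in RNA length between the arrays cannot be told apart from the pattern. The share of higher genes backed by another probe set (46.4%) and that of lower genes (40.8%) have overlapping intervals. These shares use no position of the probe sets along the transcript, so they cannot decide on RNA length. The culture condition itself stays open and untested, as does endothelial RNA of another species, which mouse probes may miss.

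The leukocyte genes near background on both arrays are the pattern that bears most on the labels. Among pan-leukocyte genes 4 of 25 were measured, at a percentile of 0.005 among random lists. Without the 5 genes that prompted the pattern, 4 of 20 were measured (percentile 0.01). These percentiles cannot decide on weak detection of such genes, because 6 of 9 lists for other lineages also lay below the lower percentile limit. Detection was not weak for all genes, since 46.4% of them reached 200. Poor probe sets for the pan-leukocyte genes alone were not tested. For B-lineage identity genes weak detection cannot be told apart, since without those 5 genes 6 of 14 were measured (percentile 6.17), too few genes to decide. RNA from cells other than leukocytes on both arrays is a candidate explanation that these data leave open: the 9 lists for other lineages lay between the percentiles 0.015 (melanocyte) and 46.1 (hepatocyte), with mesenchymal genes at 31.0, and lymphoma cells that have lost leukocyte genes cannot be told apart from other cells, since both leave the same genes dark. No biological explanation from the design was tested, because the pattern is common to both groups.

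Probe sets without a single gene symbol, which no comparison uses, were mostly higher in co-culture among those past 2-fold. Of 3996 measured, 594 were at least 2-fold higher and 177 lower (77.0% higher, exact 95% interval 73.9 to 80.0). The interval treats probe sets as independent, although all come from the same pair of arrays. They were dimmer than probe sets with 1 symbol, with median intensities of 79.1 and 357. Among probe sets with 1 symbol matched on level the share was 57.1%. This lies between the bounds set for and against low signal level as the whole cause, just short of the bound against it. That explanation therefore cannot be told apart here. The culture condition stays open and untested.

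Among the control probe sets other than the spikes, the 5′ probe set for 18S ribosomal RNA was 3.57-fold brighter on the co-culture array (660 and 2357). Its 3′ probe set had 685 and 980. The 5′ probe set for beta-actin was 2.34-fold brighter there, which in part restates the 3′ to 5′ ratio of beta-actin, since that ratio uses it.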

How the results depend on the processing

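The floor moved the counts most. With the floor at percentile 25, 2029 genes were higher and 1599 lower, 4 lists stood apart and the SD between probe sets was 0.79; at percentile 75, 143 were higher, 397 lower and the SD was 0.38; at an intensity of 200, chosen after the data were seen, 218 were higher, 656 lower and the SD was 0.43. A pseudocount of 16 gave 853 higher genes and an SD of 0.64. The SD was also 0.58 after quantile normalization, 0.65 without shared-sequence probe sets and 0.61 scaled to the spikes. The share higher among genes past 2-fold was 55.9% at the lowest floor and 41.5% with the pseudocount, against 31.2%. Without shared-sequence probe sets H2-D1 turned to 0.10 and Cd151 to 0.26; the cause was not tested. Of the other values for named genes 802 moved by less than the SD between probe sets and 127 by more, and of those for list medians 196 moved by less than the SD of random lists and 61 by more. The lists of TGF-beta and BMP response, drug efflux and detoxification, and oxidative phosphorylation stood apart in all 9 alternatives, with medians from 0.43 to 0.72, from 0.17 to 0.70 and from -0.42 to -0.16. Among the 9, subtraction of the median difference cannot change a percentile, and scaling to the spikes can do so only through the floor. Lists that did not stand apart as reported did so in 4 alternatives (unfolded protein and amino acid response, lower), 3 (FGF and IGF axis, lower), 2 (metalloproteases and invasion, higher) and 1 (pre-B and BCL2 family, higher; G2 and mitosis and histone genes, lower). Signal over background limits the rest: 144 of the higher and 170 of the lower genes had a value at or below the floor on 1 array. No paired analysis was possible because each group has 1 array.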

Other observations

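The lists and tests in this part were all chosen after the data were seen. Beside Cyp1a1, other genes known as targets of the aryl hydrocarbon receptor, a sensor of foreign and endogenous aromatic compounds, were set on the same scale. Cyp1b1, a related cytochrome, was 2.89-fold higher in co-culture (1589 to 4590), Nqo1 3.63-fold, and Ahrr, the repressor of the receptor, at least 1.82-fold. Tiparp and Nfe2l2 had log2 differences of 0.17 and 0.07. The 6 measured targets had a median of 1.20, and 0 of 10000 random lists matched on level had one as high; the list holds the genes that prompted it, and without those and the members of earlier lists 3 measured genes remain, with a median of 0.17 and 0 at least 2-fold higher, too few for a percentile.

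Lineage genes outside the blood were bright in part. Of 25 epithelial genes 12 were measured, with the desmosome gene Dsp 6.55-fold higher in co-culture (363 to 2378) and Perp at 5791 and 3152. Of 14 mesenchymal genes 8 were measured, with Twist1 at 869 and 612 and Snai2 at 1528 and 651. Of 20 neuronal genes 8 were measured, with Ncam1 at 2240 and 992, and of 12 genes of neural progenitors and glia 3, with Msi1 at 843 and 372 and Sox9 at 567 and 288. Measured members numbered 5 of 8 for hepatocyte, 4 of 14 for pluripotent, 2 of 10 for photoreceptor and retina, 1 of 10 for muscle and 0 of 8 for melanocyte genes.

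A hypothesis for the higher detoxification genes is a shift of the targets of NRF2, the transcription factor of the response to oxidants, as a group. All 13 measured targets had a median of 0.54, and 1 of 10000 random lists had one as high, but that list includes Nqo1, Hmox1 and Gclc, which prompted it. The 6 measured targets outside the earlier lists had a median of 0.49 at a percentile of 99.7, with the carbonyl reductase Cbr3 3.49-fold higher, Srxn1 at 0.87, Gsr at 0.54, Me1 at 0.45, Fth1 at 0.30 and Osgin1 at -0.28. These values are consistent with such a shift on these 2 arrays. Cultures and media that differ in ways the labels do not give could produce it as well as contact with endothelial cells, and the design cannot separate them.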
